A study of Capra hircus with 8 samples.

How the data were processed

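Total liver RNA of goats on the LC and HC diets was labelled with Cy3 and hybridised to 1-colour arrays, per the labels' protocols. All 8 arrays lay on 1 slide and were read in 1 scan, per the file headers. The authors deposited each array's scanner output as spot intensity on a linear scale, made with Agilent Feature Extraction. Its version is 10.7.1.1 per the file headers and 9.1 per the submitters' processing notes. The deposited processed signal is background-subtracted and detrended within an array, with no scaling between arrays, per the file headers. Flags deposited beside it mark spots that were saturated, not uniform, outliers of their population, or well above background. The authors also deposited a table of values that track log2 of the scanner signal. Every column of it has a median of 7.18, lower quartiles from 5.04 to 5.06 and upper quartiles from 10.07 to 10.08, so its columns share 1 distribution. How the authors normalized it is not given in the sources used here. Each column correlated best with its own array's scanner values (r across probes from 0.990 to 0.993), which gave its log2 scale and direction; its centring stays unknown.

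The main values were log2 of the processed signal minus each array's 75th percentile over probes other than controls. Spots marked as not uniform or as population outliers were left out (25 to 63 per array), and spots of a probe were averaged. A probe was kept if at least 0.5 of its spots were well above background on every array of at least 1 group. This left 40111 of 61012 probes, and for an accession with several probes the one with the highest mean was used, giving 39086 transcripts. A transcript not well above background on any array of a group has only a bound there. The bound is the mean of the other group minus the mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

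HC and LC arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Log2 differences are HC minus LC. Shares of variance, component scores and pair spreads were tested by exact permutation over the 56 ways to part 8 arrays into 3 and 5. Tested on simulated data built on these arrays, with 200 of 39086 transcripts changed in each of 10 sets, the fit recovered 27.3% of 2-fold, 76.7% of 4-fold and 98.0% of 16-fold changes. False calls made up 5.08% of its calls. Sets with no change gave at most 1 call and a median of 2030 transcripts at an unadjusted p under 0.05. The simulated noise was drawn independently for each transcript and array, so these rates do not cover noise shared between arrays or transcripts. Other splits of the real arrays into 3 and 5 gave up to 34 calls and 5336 such transcripts.

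The design, the tests, the naming rule and most alternatives were fixed before the data were examined. Named transcripts were to be those with a gene symbol and the largest changes in each direction past the threshold, together with members of 46 gene lists holding 1158 genes. The files pair no gene names with the accessions, and 0 of the probes matched the RefSeq table of goat assembly ARS1.2. The list tests were therefore not run, and 2 accessions per direction, those with the largest log2 differences past the threshold, are named.

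Alternatives were normexp background correction (offset 50), quantile and median scaling, the authors' value table, no filter or a stricter filter on dim probes, the mean over an accession's probes, every probe on its own, array weights, the trend and robust options of eBayes, HC 4 and HC 4a averaged, a plain equal-variance test, an adjusted p of 0.1, and each array left out in turn. Normexp was planned on mean spot signals, and the median spot and background signals were used because the files hold no mean spot signal. The slide could not serve as a block with 1 slide. Alternatives added after seeing the data were the row of the slide as a block, with LC 1, LC 2, LC 3 and HC 4 in row 1 and the rest in row 2, leaving out HC 4 and HC 4a together, and calls by direction. Groups shared no replicate number, so no pairing was tested.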

Results

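Liver RNA of mid-lactating goats was measured on 1-colour Agilent arrays after 9 weeks on a diet in which concentrate made up 40% (low concentrate, LC) or 60% (high concentrate, HC) of the dry matter. Goats had been assigned to the diets at random, and the comparison asks how liver transcript levels differed after long feeding on the richer diet. There were 3 LC arrays, numbered 1, 2 and 3, and 5 HC arrays, numbered 4, 5, 4a, 7 and 8. The series text counts each array as a goat, but it also speaks of 3 samples per diet, and 2 HC titles share the number 4, so p-values measure the spread between these arrays, which for HC 4 and HC 4a may be technical. Each array held 61462 spots other than controls, of which 0 were saturated. Between 64.2% (HC 5) and 71.1% (LC 3) of the 61012 probes were well above background, and the 75th percentile of the processed signal lay between 808 and 1331 intensity units. The number of arrays limits the precision of every value. The files name transcripts by sequence accession, without gene names, and 0 of the probes had an accession in the goat reference table used here, so transcripts are given by accession and the planned gene list tests have no members.

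Livers on the HC diet had higher levels at the probes of 3 transcript accessions, each by over 8-fold. GT879014 rose by 5.25 on the log2 scale (SE 0.53; 38.1-fold; limma adjusted p = 0.0156). Its scaled log2 level was -3.20 ± 1.44 (SD, n = 3) on the LC arrays and 2.05 ± 0.33 (SD, n = 5) on the HC arrays. NM_001080250 rose by 4.76 (SE 0.43; 27.1-fold; limma adjusted p = 0.00998), from 1.24 ± 1.06 (SD, n = 3) to 6.0 ± 0.40 (SD, n = 5). Its processed signal ran from 1095 to 6159 intensity units over the LC arrays and from 59490 to 92300 over the HC arrays. The last riser, left unnamed here, rose by 4.66 (SE 0.44; 25.2-fold; limma adjusted p = 0.0114). In each of these transcripts all 5 HC arrays lay above all 3 LC arrays. The LC arrays differed widely, since GT879014 stood at -1.70 on LC 1, -3.35 on LC 2 and -4.56 on LC 3. NM_001080250 stood at 2.44, 0.86 and 0.43 on the same arrays, and the unnamed riser, in the same order, at 3.11, 1.49 and 1.01. Within the diet groups, NM_001080250 and the unnamed riser correlated across arrays at r = 0.998, so this pair varied almost as a single signal. Their correlations with GT879014 were 0.913 and 0.914. Without gene names it is not known whether the 3 probes report separate genes, so they may not be 3 independent changes.

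All 3 increases missed the threshold once HC 4 and HC 4a were averaged and counted as 1 goat (limma adjusted p = 0.0539 for NM_001080250, 0.0702 for GT879014 and 0.0601 for the unnamed riser), although the log2 differences stayed at 4.66, 5.19 and 4.56. The call on NM_001080250 was also lost without LC 2 (limma adjusted p = 0.0723) or HC 4 (0.0571), and that on GT879014 without LC 2 (0.126), HC 4 (0.0741), HC 5 (0.073), HC 4a (0.0727) or HC 8 (0.0587), or with no filter on dim probes (0.061). The unnamed riser lost its call without LC 2 (limma adjusted p = 0.0926), HC 4 (0.0613), HC 5 (0.0602) or HC 4a (0.0626). The size of the increases turned on single LC arrays: without LC 1 the log2 differences were 6.01 for GT879014, 5.36 for NM_001080250 and 5.28 for the unnamed riser, and without LC 3 that of GT879014 was 4.58. With array weights they were 4.13, 3.87 and 3.74, and normexp background correction gave 4.43 for GT879014, all past the threshold. The weights rested the LC mean mainly on LC 1 (weight 4.24, against 0.399 for LC 2 and 0.472 for LC 3). LC 1 was the LC array with the highest level of each riser.

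**Figure D1:**
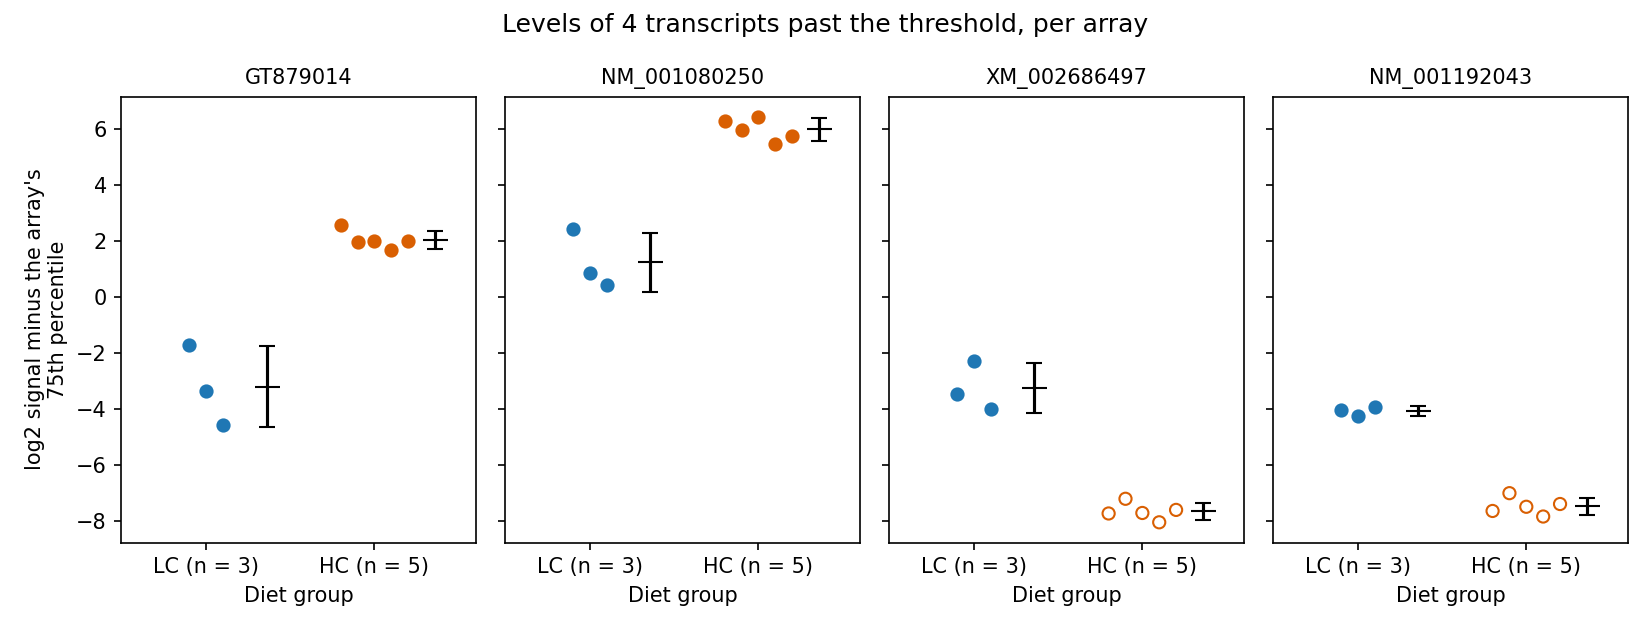
Scaled log2 signal (vertical axis, log2 units relative to each array's 75th percentile) of 4 transcripts past the threshold, by diet group. Points are arrays, bars are the mean ± SD beside them, and open points are arrays of a group in which the transcript was not well above background on any array; the HC arrays of GT879014 lie between 1.69 and 2.59, above the highest LC array at -1.70.

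Levels of 5 transcripts were lower in the HC livers. XM_002686497 was well above background on all 3 LC arrays and on 0 of 5 HC arrays, so its decrease has only a bound. By the processed signal it was at least 4.86-fold lower on HC (limma adjusted p = 0.00551), with a processed signal of 50.5 to 272 intensity units on LC and 4.05 to 6.53 on HC. NM_001192043 was measured in the same way on LC alone and was at least 2.75-fold lower on HC (limma adjusted p = 0.00124), with 53.5 to 69.6 intensity units on LC and 4.31 to 7.50 on HC. Another pair of unnamed transcripts, likewise not well above background on any HC array, was at least 2.04-fold and at least 1.96-fold lower (limma adjusted p = 0.00279 and 0.0114). The last of the fallers was measured on every array. It fell by 1.59 on the log2 scale (SE 0.18; 3.01-fold; limma adjusted p = 0.0341), from 1.00 ± 0.29 (SD, n = 3) to -0.59 ± 0.15 (SD, n = 5). Each bound sets the mean of the LC arrays against the higher of the lowest well-measured signal and the probe's own signal on each HC array. The limma p-values of the 4 fallers with a bound, here and below, take their HC signals as measured, and no bound was tested.

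None of the 5 decreases passed the threshold after normexp background correction, where the log2 difference was -1.60 for XM_002686497 (limma adjusted p = 0.0872) and -0.995 for NM_001192043 (0.638). Both lie under the bounds above, which hold for the processed signal alone, and the offset of 50 intensity units added in normexp shrinks differences between signals this dim. The faller measured on every array kept its difference there, at -1.51, and just missed the threshold (limma adjusted p = 0.054). XM_002686497 and NM_001192043 still passed with HC 4 and HC 4a averaged (limma adjusted p = 0.0363 and 0.00952) and without each array in turn, but not without both HC 4 and HC 4a (0.125 and 0.0761). The faller measured on every array was lost with the pair averaged (limma adjusted p = 0.118), with no filter on dim probes (0.127) and without any array except LC 3 (0.0921 to 0.156), while its log2 difference stayed between -1.63 and -1.47 in these settings. The unnamed faller with the bound of 1.96-fold was lost with the pair averaged (limma adjusted p = 0.0601), in the authors' values (0.106) and without LC 1 (0.0586), LC 2 (0.0769), HC 4 (0.0613) or HC 4a (0.0626). With its dim HC signals taken as measured, its log2 difference there lay between -3.09 and -2.89, except for -1.53 in the authors' values.

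Few transcripts passed the threshold between the livers of both diets. Of the 39086 transcripts tested, 8 passed an adjusted p of 0.05 in limma, 3 of them higher and 5 lower in HC. At an adjusted p of 0.1 there were 15. The median log2 difference was -0.03, with quartiles of -0.21 and 0.14, and 98.2% of transcripts lay within 2-fold. An unadjusted p under 0.05 was reached by 2372 transcripts, where 1954 were expected by chance, and 410 of these also differed by at least 2-fold. The same counts were 6600 and 1064 with array weights, 3752 and 670 without LC 2, and 1799 and 152 with normexp. Of the 2372, 973 were higher and 1399 lower in HC. The balance of directions changed with the values used, each of which gives its own set of transcripts at an unadjusted p under 0.05: 1362 were higher and 928 lower with quantile normalization, and 1364 higher and 895 lower in the authors' values. Of the 410, 111 were higher and 299 lower, while the sets chosen in the same way held 160 higher and 201 lower with quantile normalization and 101 higher and 154 lower in the authors' values. The count of 8 became 55 with array weights (23 higher and 32 lower) and 3 with normexp (3 higher and 0 lower). It became 3 with HC 4 and HC 4a averaged, 3 without HC 4, 4 without HC 4a, 5 without HC 5 and 13 without LC 3. With both HC 4 and HC 4a left out it was 0, and limma gave 2042 transcripts at an unadjusted p under 0.05. A plain equal-variance test on the same values gave 0 after adjustment and 2440 at an unadjusted p under 0.05. With the row of the slide as a block, an alternative chosen after seeing the data in which HC 4 is the only HC array beside the LC arrays, 137 transcripts passed, among them GT879014 (limma adjusted p = 0.039), NM_001080250 (0.0314), XM_002686497 (0.0292) and NM_001192043 (0.00756).

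Transcripts were also counted by the kind of sequence record behind the probe. RefSeq mRNA records (prefix NM) gave 10222 tested transcripts, of which 5 passed the threshold and 5.94% had an unadjusted p under 0.05. Predicted mRNA records (prefix XM) gave 6622 tested transcripts with 1 past the threshold and 6.09% at an unadjusted p under 0.05. For the 20419 transcripts under other accessions these values were 2 and 6.14%. Non-coding RefSeq records numbered 890, with 0 past the threshold in limma and 60 (6.74%) at an unadjusted p under 0.05. Probes without an accession numbered 933, with 0 past the threshold in limma and 49 (5.25%) at an unadjusted p under 0.05. Fewer predicted and non-coding records were measured, since 45.1% and 47.2% of their probes passed the filter on dim probes, against 73.2% of the mRNA records.

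Diet accounted for 16.5% of the variance over transcripts, against a median of 13.8% and a highest value of 23.7% over the other ways to part 8 arrays into 3 and 5 (exact permutation p = 0.232 over 56 splits, upper tail). Principal component 1, with 27.0% of the variance, set HC 4 (score 71.8) and HC 4a (67.7) apart from the rest, whose scores lay between -46.7 and 11.5, and did not separate the diets (two-sided exact permutation p = 0.536). Component 3, with 15.8% of the variance, placed all 3 LC arrays between 16.1 and 62.3 and all 5 HC arrays between -47.3 and -8.05. Its two-sided exact permutation p of 0.0179 was the smallest that 56 splits allow, and 0.0714 after Benjamini-Hochberg adjustment over 4 components. These splits count HC 4 and HC 4a as separate goats, and the components were not tested with the pair averaged.

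**Figure D2:**
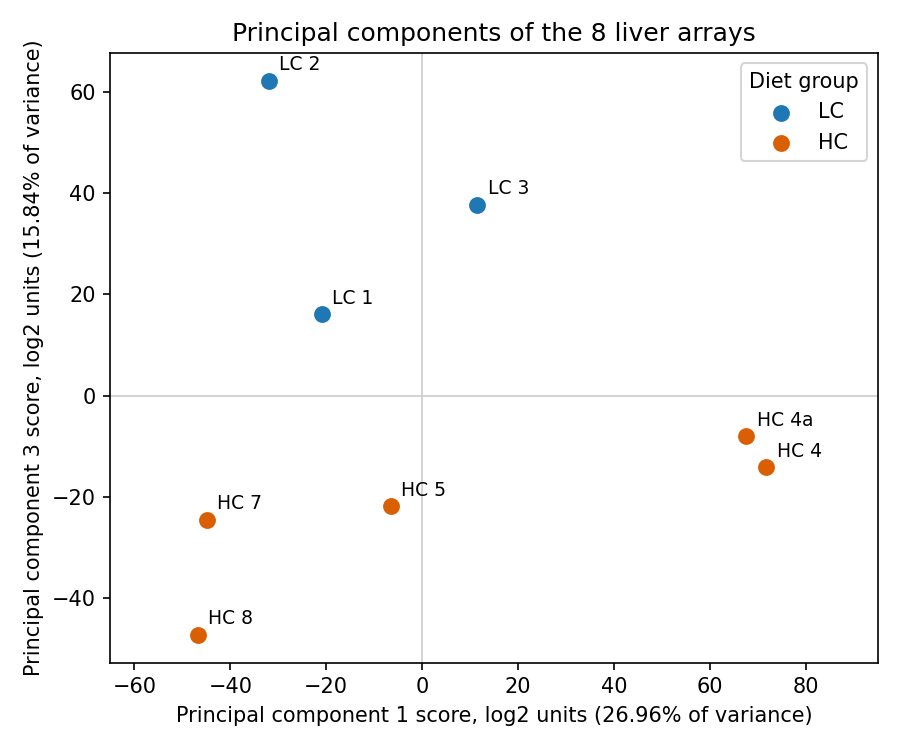
Scores of the 8 arrays on principal component 1 (horizontal axis, 26.96% of the variance) and component 3 (vertical axis, 15.84%), in log2 units, coloured by diet group. HC 4 and HC 4a lie together at scores of 71.8 and 67.7 on component 1, and the LC arrays have positive and the HC arrays negative scores on component 3.

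The spread between pairs of livers overlapped within and between diets. Over probes well above background on all arrays, the SD of the log2 difference averaged 0.610 over the 15 pairs of different diets, 0.559 over the 10 HC pairs and 0.657 over the 3 LC pairs. The mean between diets exceeded that within diets by 0.028 (exact permutation p = 0.0893, upper tail, with 5 of 56 splits as large). The mean within diets includes HC 4 and HC 4a, which may be 1 goat, and the splits count them as separate goats. The excess was not recomputed with these arrays averaged, so part of it may come from that pair. The closest pair was HC 4 and HC 4a, with an SD of 0.419, followed by HC 7 and HC 8 with 0.486. A rule set before the data were examined counted HC 4 and HC 4a as 1 goat if their SD was under 0.5 times that of the next pair. It was not met, so both were kept as samples. Failing this rule does not show that they were 2 goats. Within an array, the difference of 2 spots of a probe had an SD of 0.425 on HC 4 and 0.154 on HC 4a. A repeat of 1 goat could therefore fail the rule too.

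**Figure D3:**
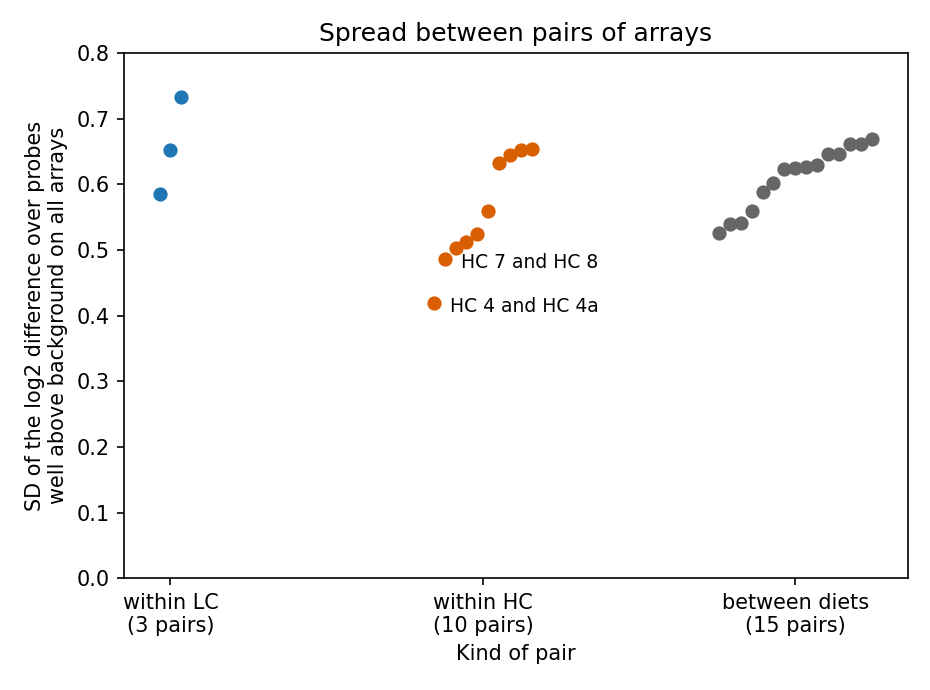
SD of the log2 difference between 2 arrays (vertical axis, log2 units, from 0) for each of the 28 pairs, grouped by whether both arrays were LC, both HC or of different diets. Each point is a pair; HC 4 and HC 4a lie lowest at 0.419, and the pairs of different diets lie between 0.526 and 0.670.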

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

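The test of uneven signal given here was chosen after the result was seen. HC 4 had 63 spots marked as outliers by the scanner software, against 25 to 29 on the other HC arrays, all in row 2 of the slide, and 41, 31 and 36 on LC 1, LC 2 and LC 3, with which HC 4 shares row 1, so that the count runs with the row, which stays open as a source; from the other HC arrays it stood apart by a gap of 0.895 of the group's range. It was the only 1 of 16 measures over the HC arrays in which an array stood this far apart, and chance flags about 5% of such groups. Over 27 probes with 10 spots that were well above background on all arrays, the SD of the difference of 2 spots of a probe was 0.425 (log2) on HC 4, against 0.154 on HC 4a and at most 0.303 elsewhere. Over all 50 probes with 10 spots, dim ones included, it was 0.733 on HC 4, under LC 3 (0.832) and LC 1 (0.775). It stood alone, over 8-fold from all other arrays, at 17 transcripts, against 2 to 8 on the other HC arrays, while LC 1 did so at 32.

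A candidate source of the stray spots on HC 4 is signal that was uneven over the array. The difference between the authors' values and the processed signal ranged by 0.492 (log2) over regions of HC 4 and by at most 0.480 on the other arrays, an excess too small to decide. HC 4 was still the array where these values matched least. Over probes well above background on all arrays, their deviations from the mean over arrays correlated at 0.8832 on HC 4, against 0.9715 to 0.9873 elsewhere. That does not show whether the mismatch followed regions of the array. No biological explanation was tested, since diet is shared with the other HC arrays.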

How the results depend on the processing

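The slide row, the joint omission of HC 4 and HC 4a, and calls by direction were chosen after seeing the data. Over 172 values of the 8 called transcripts under alternatives, 0 changed direction, 119 stayed past the threshold and 53 did not. Part of this was fixed in advance. All 8 have 1 probe on the array, so averaging probes or testing each on its own could not move their differences. Both filter alternatives, the eBayes options and the plain test also leave the log2 differences as they were, so direction could not change there. In all 8 the diets did not overlap, so leaving out arrays, averaging HC 4 and HC 4a or weighting arrays could not reverse a difference either. Direction could change only with other scalings, normexp, the authors' values or the slide row as a block. The 8 calls became 3 with normexp, 4 with only probes well above background on all arrays (which removes the 4 fallers dim on HC), 55 with array weights (4.24 for LC 1, 0.399 for LC 2), 3 with HC 4 and HC 4a averaged, 0 with the plain equal-variance test (2440 at an unadjusted p under 0.05), 15 at an adjusted p under 0.1, 137 with the slide row as a block and 0 without both HC 4 and HC 4a. With the row as a block the comparison within a row rests on HC 4 alone, and 6 of the 8 calls were among the 137. The authors' values gave 9 calls, 7 of them shared. The 2372 transcripts at an unadjusted p under 0.05 became 6600 with array weights. The 410 that also differed 2-fold became 152 with normexp, 255 in the authors' values, 901 with no dim filter, 245 with only probes above background on all arrays, 1064 with array weights, 240 with the plain test and 1462 with the row as a block. Leaving out each array in turn gave 3 (without HC 4) to 13 (without LC 3) calls, 1895 (HC 4a) to 3752 (LC 2) transcripts at an unadjusted p under 0.05, and 359 (HC 4a) to 670 (LC 2) with 2-fold. The cause was not tested except where stated. The share of variance between diets, recomputed where a setting changes the values or the arrays, stayed short of the threshold (exact p from 0.143 to 0.464); without both HC 4 and HC 4a the splits are too few to pass it. Signal over background limits the fallers, which rest on LC signals of 20.8 to 272 intensity units apart from the one measured on all arrays. All gene list alternatives and the slide as a block were not run; counting HC 4 and HC 4a as 2 goats is the main design. No paired analysis was possible because the groups share no replicate number.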

Other observations

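Tests here that were chosen after the result was seen are the filters other than that of the diets in the splits, the splits for the 2372 and 410 transcripts, both tests of the slide row (that of HC 4 replaced a test set in advance over all 8 calls, void since HC 4 helped to make them), the count over 8-fold among transcripts measured on all arrays, and the count of transcripts with 2 levels. Transcripts well above background on all 3 LC arrays and 0 of 5 HC arrays numbered 48, and those on all 5 HC and 0 of 3 LC arrays numbered 0. Over other splits of the arrays into 3 and 5, counts of the first kind had a median of 9 and reached 111, and those of the second kind had a median of 8 and reached 110. Diets did not overlap in 1803 transcripts, 773 higher and 1030 lower in HC, which is 4.61% of those tested against 3.57% by chance.

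The 8 calls between diets were set against other splits of the arrays into 3 and 5, with the filter on dim probes redone in each; of the 6 splits with HC 4 and HC 4a in the group of 3, 3 gave more calls than diet (34, 21 and 9) and the rest gave 2, 2 and 0. As many calls came from 4 of 56 splits, the real one included (highest other 34, for LC 2 with HC 4 and HC 4a), and with that pair averaged 2 of 35 splits, the real one included, gave as many calls as its 3 (highest other 3), so chance could not be excluded. This turns on the filter: with that of the diets kept in every split, which favours the real one, the counts were 2 of 56 and 1 of 35, both under the 5% set in advance, and with no filter or only probes well above background on all arrays, filters blind to diet, 3 of 56. The row of the slide stays open, since HC 4 is the only HC array in the row of the LC arrays, although over the 3 transcripts called without it HC 4 showed a median of 1.02 times the difference of the remaining HC arrays from LC. These 3 were all fallers not well above background on any HC array, so the value rests on HC signals near background and holds no riser. Sequence or copy variants that switch a probe on or off in single goats may contribute, and an effect of diet stays open beside them. Other splits gave up to 30 transcripts over 8-fold apart without overlap, against 13 for diet (17 against 16 with the pair averaged). Each other split of the 8 arrays with as many as diet held HC 4 and HC 4a together in its group of 3. With the pair averaged, 2 of 35 splits, the real one included, had as many. The counts cannot tell such variants from other differences between goats.

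For the 2372 transcripts at an unadjusted p under 0.05, 15 of 56 splits gave as many (highest other 5336), and for the 410 with 2-fold 15 splits did (highest other 994), so chance could not be excluded for either count.

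HC 4 and HC 4a resembled each other more than any other pair, and their deviations from the mean over all arrays correlated at 0.443 across transcripts, which are not independent replicates, against 0.187 for the next pair. They lay in 2 different rows of the slide, which argues against a shared row. A single goat arrayed 2 times may lie behind them: they differed by over 8-fold at 55 transcripts, where under 0.5 times the 63 of the next pair had been predicted, but 26 of the 55 were not well above background on HC 4 or HC 4a, where that bound took both levels as measured, and among transcripts well above background on all arrays the counts were 17 and 36. At 45 of the 55, HC 4, the array with the stray spots above, lay farther from the remaining arrays, and at 10 HC 4a did. The SD of the difference between HC 4 and HC 4a was 1.37 times that of 2 spots of a probe (95% bootstrap interval 1.00 to 2.09). This leaves open whether 1 labelled sample was hybridised 2 times. For 2 unrelated goats, transcripts with 2 levels at least 4-fold apart were counted. Those well above background on all 8 arrays parted HC 4 from HC 4a 1 time, against at least 4 for other pairs within a diet. Of these 33 transcripts, 14 set HC 4 and HC 4a together apart from the other 6 arrays, a count not made for other pairs. Minimums of 7, 6, 5 and 4 arrays gave 1, 2, 3 and 6 against at least 6, 11, 14 and 18. A minimum of 3 arrays gave 20 against 37, and 2 arrays, the dimmest set, 99 against 81. These last sets admit transcripts not well above background on most arrays. The test asked for under 0.5 times as many at every minimum, so whether they were unrelated goats stays open.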
